A study of Homo sapiens with 5 samples.

How the data were processed

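Lymph node sections from 5 human biopsies, all labelled as admixed follicular lymphoma (FL) and transformed follicular lymphoma (tFL), were measured with Visium HD, a probe-based assay that reads RNA in fixed tissue on a grid of 8 µm bins. The deposited matrices hold raw UMI counts (unique molecular identifiers, so amplified copies of a molecule count once) per gene and bin, 1 section per biopsy, with no normalization. For biopsy 5 the title and the name of the files disagree. The files linked to that sample were used, so which biopsy its values belong to is in doubt. Per the labels the authors ran Space Ranger 3.0.1; the file headers name version 3.0.0 in 4 matrices and 3.0.1 in 1. The genome build is not given in the sources used here, so no coordinates are printed, and the identifiers used are the gene symbols in the deposited gene tables. Each matrix lists 18085 genes, of which 17997 symbols matched the reference table, 3 after an update of the symbol. XIST and Y-linked genes (16 listed) were left out before any sum. Image scale factors were not used here, and no region annotation, image or mutation data were used.

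Tissue was divided into square tiles of 12 bins (96 µm) and areas of 5 by 5 tiles (480 µm). A tile was kept with at least 75% of its bins listed, UMIs per bin of at least 10% of the 90th percentile over the biopsy's tiles, and at least 1000 UMIs. An area was kept with at least 13 of its 25 tiles. This kept 3977, 4807, 4256, 4093 and 4737 tiles and 163, 196, 171, 169 and 189 areas in biopsies 1 to 5. Areas were ranked within each biopsy by the summed CPM (counts scaled to a total of 1e+06 UMIs) of 37 proliferation genes. The highest and lowest of 3 equal classes were called high and low proliferation areas (54, 65, 57, 56 and 63 areas per class). They are ranges of that score, not the pathologists' regions. Tiles were ranked by log2 of the B lineage list CPM plus 1 over the T lineage list CPM plus 1, and the highest and lowest of 3 classes were called B-rich and T-rich tiles. A class needed at least 10 tiles.

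UMI counts were summed per biopsy and class, and the biopsy was the replicate. Both sums of a biopsy come from the same section, so the biopsy was a block in every fit. The sums held 15493630 to 51220856 UMIs for areas and for tile classes, and 685530 to 32813726 when each area class was divided by tile class; the thinnest was biopsy 4's B-rich tiles in low areas, with 30 tiles. For the median gene, counting error made up 9.63% of the variance of the log2 difference between biopsies for areas and 13.9% for tile classes. It made up 34.0% within B-rich tiles, 46.2% within T-rich tiles and 61.3% for the difference. Intervals are given as the standard error (SE) of the fitted log2 fold change, which is its size over the square root of edgeR's F statistic. The variance behind it is shared in part across genes. It is not the spread over biopsies and can be smaller than the standard error which that spread gives. Genes passing filterByExpr were tested with the edgeR 4.0.16 quasi-likelihood test, TMM scaling and Benjamini-Hochberg adjustment at 0.05. Genes of the B and T lineage lists were not tested between tile classes, and genes of the proliferation list were not tested in the other comparisons. Within B-rich and T-rich tiles and for the difference, B and T lineage genes were tested although their ratio had picked the tiles. Log CPM used a prior count of 2. The 5 comparisons were high against low proliferation areas, T-rich against B-rich tiles, the area comparison within B-rich and within T-rich tiles (1 model with 4 sums per biopsy), and the difference between these effects. That model left 12 residual degrees of freedom, against 4 in the fits of 2 sums per biopsy. It does not model an area effect that the B-rich and T-rich tiles of a biopsy share. The SE and p of its area effects may thus be too small.

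The 33 gene lists covered proliferation, B lineage, T lineage, further cell cycle genes, germinal centre B cells, activated B cells with NF-kB targets, naive and mantle B cells and plasma cells. T cell lists were follicular helper T cells, cytotoxic CD8 T and NK cells, exhaustion genes, regulatory T cells, and naive and central memory T cells. Other cell lists were macrophages, dendritic cells, follicular dendritic cells, fibroblasts, T zone stroma, endothelium, granulocytes with mast and red cells, and epithelium with fat. Program lists were interferon gamma response, type I interferon response, cytokines, chemokines, MYC targets, glycolysis and hypoxia, oxidative phosphorylation, MHC class I, MHC class II, checkpoint ligands, genes recurrently altered in FL, and stress and immediate early genes. Some lists share members: chemokines overlap with the cytotoxic, T zone and interferon gamma lists. The MHC class II list had 1 of 11 members in the deposited tables (CD74) and was not tested. Lists were tested with camera (limma 3.58.1) on log CPM with a preset correlation of 0.01 between genes, with camera using an estimated correlation, and with fry. Camera compares a list with the other genes; fry tests whether a list's genes move one way on balance. Across tiles, 13 pairs of lists were compared by Spearman correlation within each biopsy. The mean Fisher z over biopsies was tested with an exact two-sided sign-flip permutation test, whose smallest possible p with 5 biopsies is 1 in 16.

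The lists, scores, classes, comparisons, tests and naming rule, and the alternatives not named otherwise here, were fixed before the data were examined. The naming rule took, per comparison, the 10 largest changes in each direction among genes past the threshold with 1 sign in every biopsy and at least 20 CPM on average, leaving out proliferation, other cell cycle, immunoglobulin and T cell receptor segment genes. It also took up to 4 members of each list with the smallest p, and in every comparison IFNG, CXCL9, CXCL10, CXCL13, CD8A, LAG3, FOXP3, CD68, CR2, CCL19, CCL21, MYC and BCL2, 13 genes in all. The genes printed singly are part of those the rule took (39 of 125 in the area comparison and 46 of 138 between tile classes), picked after their values were seen. CXCR5 stands outside the rule and was also named after its values were seen.

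Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, no low count filter, no replicate block, and each biopsy left out in turn. They were also a tissue threshold of 25%, tiles of 6 or 20 bins, tiles in the middle of the biopsy's UMIs per bin, 2 or 4 classes in place of 3, areas of 240 µm together with tiles of 6 bins, and an area score divided by the B lineage list. For correlations they were Pearson, a partial correlation given log UMIs per tile, and the same changes of tile and threshold. After the data were seen, these were added: biopsies 2, 3 and 5 alone, biopsies 1, 3 and 4 alone, biopsies 1 and 2 alone, biopsies 3 to 5 alone, genes with split detection left out (also from list levels), and list scores by mean rank. Added after as well were tiles of high and low areas drawn in equal numbers from 40 strata of UMIs per bin within each biopsy, and list medians in 30 moved or mirrored score maps. So were correlations of the interferon gamma response list without its 4 most abundant members and given the log ratio of the B to the T lineage list, with a 95% range over 400 draws of areas. Gene lists were planned for DESeq2 size factors, an estimated correlation, fry and biopsies left out, and their other alternatives were added after. Sets of biopsies 1 and 2 and of biopsies 3 to 5 were formed because 178 genes were at least 10-fold higher in both biopsies of the first set than in each of the other, and 0 the other way. The labels give no such batch.

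The edgeR test was checked on simulated counts with the same depths and the same spread per gene. Genes were drawn independently of each other, with the same change in every biopsy and most genes unchanged. Differences between biopsies that many genes share are absent there, so the rates need not hold for the real sums. Of 50 genes changed 2-fold, 76% were recovered for high against low proliferation areas, 98% for T-rich against B-rich tiles, 58% within B-rich tiles, 64% within T-rich tiles and 22% for the difference. At 4-fold these were 100%, 100%, 100%, 98% and 90%. Of all calls in these simulations, 18 of 161, 12 of 176, 6 of 150, 7 of 148 and 3 of 109 were of unchanged genes. R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.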

Results

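Lymph node tissue from 5 biopsies was profiled, 1 section each, with a whole-transcriptome probe panel on a grid of 8 µm bins. The labels put all 5 biopsies in 1 group, lymph nodes in which FL, an indolent B cell lymphoma, and tFL, its aggressive transformed form, are admixed. No map of the FL and tFL regions was used here, so FL was not compared with tFL. The comparisons lie within each section, between ranges of an expression score. Biopsies 1 to 5 held 129806277, 117599451, 48641570, 118765498 and 56543317 UMIs in 582846, 701837, 625873, 631346 and 681787 bins. The medians were 204, 165, 75, 168 and 79 UMIs per bin.

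To describe which cell types and programs each biopsy held, the summed level of each list was set side by side across biopsies, without a test since there is 1 group. The B lineage list was at 6587 ± 1734 CPM (mean ± SD, n = 5) and the T lineage list at 4531 ± 1211 CPM, with biopsy 1 lowest at 2452 CPM. Proliferation genes were at 2916 ± 1215 CPM and highest in biopsy 1 (4789 CPM). Biopsy 1 also had the highest level of MYC targets, 3274 CPM against 1144 to 1384 CPM in the others. Of this list, NCL and FBL were at least 10-fold lower in biopsies 3 to 5 than in biopsies 1 and 2, and without them the levels were 2647 CPM and 1122 to 1364 CPM. The same held for PAX5 of the B lineage list, which was at 6445 ± 1786 CPM without it. Cytotoxic genes ranged 7.43-fold between biopsies, from 442 CPM in biopsy 5 to 3286 CPM in biopsy 4. Fibroblast genes were at 7214 CPM in biopsy 1 and 604 CPM in biopsy 3. Dendritic cell genes were at 2986 CPM in biopsy 2 and 116 to 390 CPM in the others. Of the 2986 CPM, the chemokines CCL17 and CCL22 made up 2670 CPM. The other 10 members were at 317 CPM, within the 72.8 to 326 CPM of the other biopsies. The interferon gamma response list, genes induced by the cytokine IFNG, ranged 1.49-fold, from 4108 to 6142 CPM. Of the 33 lists, 27 differed more than 2-fold between the highest and lowest biopsy, and 17 did without biopsy 1.

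To ask how tissue with more proliferation gene counts differed from tissue with fewer in the same section, high proliferation areas were compared with low proliferation areas. The proliferation list was 3.75, 1.48, 2.08, 2.25 and 1.34 times as high in high as in low areas of biopsies 1 to 5. It was at 6760, 2388, 2817, 2913 and 4024 CPM in high areas and at 1805, 1615, 1352, 1292 and 2996 CPM in low areas. The classes are relative to each section: the low areas of biopsy 5 lay above the high areas of biopsies 2, 3 and 4. MYC target genes, which serve ribosome biogenesis and nucleotide supply, had a median log2 fold change of 0.73, with medians of 0.14 to 1.87 in the biopsies, above 0 in 5 of 5. All 15 measured members were past the threshold adjusted over the list alone, and 0 over all genes tested (adjusted p of 0.688 for the list with an estimated correlation). NME1, a nucleoside diphosphate kinase, was at a log2 fold change of 1.48 ± 0.36 (SE, n = 5), and SRM, spermidine synthase, at 1.17 ± 0.32. Respiratory chain genes had a median of 0.69, above 0 in 5 of 5 biopsies, with 20 of 22 past the threshold adjusted over the list alone. ATP5F1B of the mitochondrial ATP synthase was at 0.94 ± 0.21 and COX6C of cytochrome c oxidase at 0.71 ± 0.16. Glycolysis and hypoxia genes had a median of 0.39 (3 of 12 adjusted over the list alone), with the glycolytic enzymes PKM at 1.17 ± 0.27 and ENO1 at 1.15 ± 0.28.

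Medians of the germinal centre, activated B cell, FL gene and B lineage lists were above 0 in high against low proliferation areas. Of their members 0 passed the threshold over all genes. Medians of naive and mantle B cell and of plasma cell genes were below 0. The direction depends on the score: divided by the B lineage list, the score gave medians of -0.75 for B lineage and -0.25 for germinal centre genes, with BCL6 at -0.22 and S1PR2 at -0.0606. Dividing by that list favours areas poor in B lineage genes, so these lower medians follow in part from how the score was built. With an estimated correlation 0 lists passed. Germinal centre B cell genes had a median of 0.88, above 0 in 4 of 5 biopsies (6 of 14 adjusted over the list alone). Among them the transcriptional regulator LMO2 was at 1.42 ± 0.32, BCL6, a repressor that germinal centre B cells need, at 0.93 ± 0.24, and S1PR2, a receptor that keeps B cells in the germinal centre, at 0.84 ± 0.18. Activated B cell and NF-kB target genes had a median of 0.52 (8 of 15 adjusted over the list alone), with the NF-kB subunit RELB at 0.84 ± 0.19 and CD83 at 1.15 ± 0.33. Genes recurrently altered in FL had a median of 0.39, above 0 in 5 of 5 biopsies (6 of 16 adjusted over the list alone). The kinase PIM1 was at 1.10 ± 0.23, the histone methyltransferase EZH2 at 1.19 ± 0.30 and MYC at 0.80 ± 0.25. The B lineage list had a median of 0.50, with 0 of 15 past the threshold adjusted over the list alone. Without biopsy 4 its median was 0.20 and it was not past the threshold (adjusted p = 0.0654). Cell cycle genes outside the score, which are not independent of it, had a median of 0.99 (28 of 33 adjusted over the list alone), with UHRF1 at 1.65 ± 0.35.

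T cell, vascular and type I interferon genes had medians below 0 in high against low proliferation areas, with 0 members past the threshold over all genes. Adjusted p of the T lineage, cytotoxic, endothelial, type I interferon and chemokine lists was 0.688 with an estimated correlation. The T lineage list had a median of -0.86, above 0 in 1 of 5 biopsies (3 of 16 adjusted over the list alone). The naive and memory T cell genes TCF7 and IL7R were at -1.33 ± 0.43 and -0.82 ± 0.17. Cytotoxic genes had a median of -0.70 (8 of 15 adjusted over the list alone), with CD8A at -0.90 ± 0.27 and the granzyme GZMA at -0.72 ± 0.20. With the score divided by the B lineage list, cytotoxic genes passed in the other direction (0.30, adjusted p = 6.20e-10), with CD8A at 0.30, GZMA at 0.27 and IL7R at 0.0295. That score favours areas poor in B lineage genes, so this direction is not independent of its divisor. Type I interferon response genes had a median of -0.56, below 0 in 5 of 5 biopsies (9 of 19 adjusted over the list alone). XAF1 was at -0.69 ± 0.17 and the antiviral enzyme OAS3 at -0.54 ± 0.14. Endothelial genes had a median of -0.63 (3 of 13 adjusted over the list alone), with VWF at -0.89 ± 0.27. The chemokine list had a median of -0.38, below 0 in 5 of 5 biopsies (1 of 31 adjusted over the list alone). CXCL12, made by stroma, was at -1.24 ± 0.26 and CCL21, which draws T cells into the T zone, at -1.63 ± 0.60. Follicular helper T cell genes had a median of -0.66 (0 of 10 adjusted over the list alone, adjusted p = 0.0310, and 0.737 with an estimated correlation), and -0.31 without biopsy 1 (adjusted p = 0.0868). Epithelium and fat genes had a median of -0.56 (1 of 8 adjusted over the list alone, adjusted p = 0.0414, and 0.688 with an estimated correlation), and -0.33 without biopsy 1 (adjusted p = 0.103). FABP4, a fatty acid binding protein of fat cells, was at -1.26 ± 0.29.

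Interferon gamma response genes moved in opposite directions in different biopsies: the median was 0.06, with -0.86, -0.25, 0.38, 0.63 and 0.06 in biopsies 1 to 5 (adjusted p = 0.322; -0.18 scaled by library size alone). Without biopsy 1 it was 0.26 (adjusted p = 0.0409). IFNG itself was at -0.36 ± 0.19, and the chemokines it induces, CXCL9 and CXCL10, were at 0.15 ± 0.45 and 0.04 ± 0.31 (-0.07 and -0.20 when scaled by library size alone). Macrophage genes had a median of 0.04 and a mean of -0.01 (adjusted p = 0.661; -0.21 scaled by library size alone). CD163, a scavenger receptor, was at -1.12 ± 0.27, CD68 at 0.50 ± 0.26 and SPP1, osteopontin, at 0.96 ± 0.50. CXCL13 was at 0.17 ± 0.41 and CCL19 at 0.09 ± 0.20 (-0.06 and -0.15 when scaled by library size alone). CR2 was at 0.63 ± 0.37, LAG3 at -0.20 ± 0.17, FOXP3 at -0.51 ± 0.34 and BCL2 at -0.28 ± 0.62. With the score divided by the B lineage list, CD163 was at 0.90, IFNG at 0.16, LAG3 at 0.46, CXCL13 at -0.47 and CR2 at -0.59, each of the other sign. Naive and mantle B cell genes had a median of -0.60 (adjusted p = 0.0668), with adjusted p of 0.00943, 0.0457 and 0.0497 without biopsies 2, 4 and 5. Naive and central memory T cell genes had a median of -0.66 (adjusted p = 0.0723), with adjusted p of 0.0433 and 0.0267 without biopsies 2 and 5. Also not past the threshold were 4 lists that change sign with library size alone: checkpoint ligands (0.14 and -0.11), MHC class I (0.22 and -0.03), fibroblasts (0.12 and -0.13) and follicular dendritic cells (0.02 and -0.22). The others were cytokines (-0.25), regulatory T cells (-0.22), exhaustion genes (-0.19), T zone stroma (-0.57), granulocytes (-0.46) and dendritic cells (-0.28). Plasma cell genes had a median of -0.14 while their test pointed up (adjusted p = 0.827). Stress and immediate early genes had a median of -0.28, with 2 members higher and 4 lower when adjusted over the list alone, and FOS at -1.32 ± 0.24.

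In high against low proliferation areas 0 of 17987 genes passed the edgeR test. An unadjusted p under 0.05 was reached by 6583 genes (2695 without biopsy 4), and the DESeq2 test called 1991 (1326 up, 665 down). Adjusted p = 0.114 held for each gene named with a value except CCL21 (0.115), CD68 (0.177), SPP1 (0.181), IFNG (0.190), CR2 (0.214), FOXP3 (0.267), LAG3 (0.383), BCL2 (0.743), CCL19 (0.744), CXCL13 (0.758), CXCL9 (0.803) and CXCL10 (0.927). The list calls are camera's with the preset correlation, and with an estimated one 0 lists passed. They had adjusted p = 4.45e-16 for cell cycle, 9.08e-11 for oxidative phosphorylation, 4.93e-08 for MYC targets, 0.000148 for germinal centre and 0.000321 for activated B cell and for type I interferon genes. They had adjusted p = 0.000687 for FL and for T lineage genes, 0.00158 for cytotoxic, 0.00165 for endothelial, 0.00763 for B lineage, 0.00972 for glycolysis and 0.0110 for chemokine genes. Adjusted p was 0.737 with an estimated correlation for follicular helper T cells, and 0.688 for each other called list. The smallest adjusted p of fry was 0.174.

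In biopsies 1 and 2 alone and in biopsies 3 to 5 alone, the area medians were 1.03 and 0.56 for MYC targets, 0.91 and 0.51 for oxidative phosphorylation, and 1.07 and 0.53 for germinal centre genes. They were -1.45 and -0.56 for T lineage, -1.01 and -0.41 for cytotoxic, -0.94 and -0.33 for type I interferon, and -0.51 and 0.37 for interferon gamma genes. Biopsies 1 and 2 alone gave 116 genes past the threshold (86 up, 30 down) and biopsies 3 to 5 alone 0. The former fit rests on 2 biopsies, under the 3 set as the least for a fit, so its count is not firm. The directions of B and T cell lists depend on the score, and dividing it by the B lineage list favours areas poor in B lineage genes. With proliferation divided by the B lineage list, medians were -0.05 for T lineage and 0.30 for cytotoxic genes. MYC targets were then at 0.28, oxidative phosphorylation at 0.22 and type I interferon genes at -0.18. Scaling by library size alone moved the median of all genes from -0.10 to -0.35. It ended the calls of the chemokine (adjusted p = 0.0703), follicular helper T cell (0.214) and epithelium lists (0.214).

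**Figure D1:**
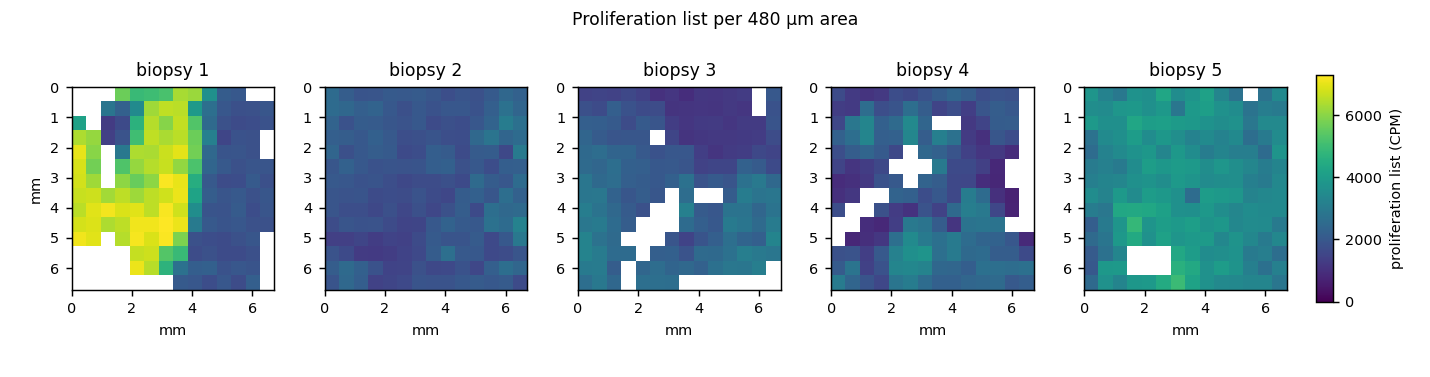
Maps of the 480 µm areas of biopsies 1 to 5, coloured by summed CPM of the proliferation list on a shared scale, with axes in mm. Biopsy 1 holds 77 areas at 5000 CPM or more and 74 under 3000 CPM, and no other biopsy holds an area at 5000 CPM or more.

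**Figure D2:**
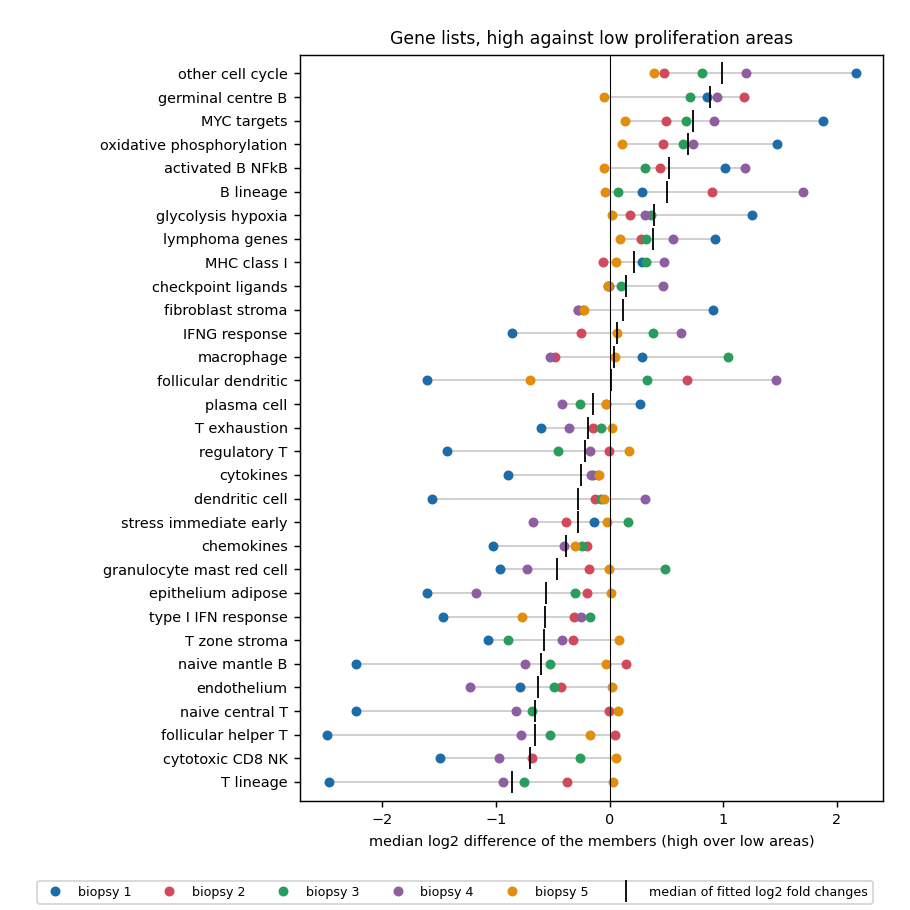
Median log2 fold change of each gene list between high and low proliferation areas, with 1 point per biopsy and a bar for the value of the fit over 5 biopsies. MYC targets (0.73), oxidative phosphorylation (0.69) and cell cycle genes (0.99) lie above 0 in 5 of 5 biopsies, and type I interferon response genes (-0.56) below 0 in 5 of 5.

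To describe how tissue rich in T cells differed from tissue rich in B cells, T-rich tiles were compared with B-rich tiles, which are ranges of an expression ratio and not drawn compartments, and log2 fold changes above 0 are higher in T-rich tiles. T cell and B cell genes outside the ratio are not independent of it. Their rise or fall follows in part from how the tiles were picked. Most cytotoxic genes rose in T-rich tiles (adjusted p of 0.347 for the list with an estimated correlation), with a median of 1.22, above 0 in 5 of 5 biopsies, and 12 of 15 members past the threshold (15 adjusted over the list alone). CD8A was at 1.49 ± 0.32 (SE, n = 5), the granzyme GZMK at 1.39 ± 0.24, the transcription factor EOMES at 1.43 ± 0.24 and the chemokine CCL5 at 1.10 ± 0.16. Exhaustion genes had a median of 0.68 (4 of 8 rose, 6 adjusted over the list alone), with the inhibitory receptor TIGIT at 0.97 ± 0.16, while LAG3 was at 0.96 ± 0.29 (adjusted p = 0.0634). Cytokines had a median of 0.16 (7 of 42 rose, and 12 adjusted over the list alone). IFNG was at 0.65 ± 0.16 and FASLG, which kills cells bearing FAS, at 1.04 ± 0.20. Regulatory T cell genes had a median of 0.46 (1 of 9 rose, 4 adjusted over the list alone), with FOXP3 at 0.80 ± 0.18. Naive and central memory T cell genes had a median of 0.74 (3 of 8 rose, 4 adjusted over the list alone). Follicular helper T cell genes had a median of 0.58 (5 of 10 rose, 6 adjusted over the list alone), with SH2D1A at 1.30 ± 0.21. In the same list 1 gene fell, CXCR5, which B cells also express.

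Part of the endothelial, chemokine, macrophage and type I interferon genes also rose in T-rich tiles. For these 4 lists as a whole, adjusted p was 0.347 with an estimated correlation. Endothelial genes had a median of 0.89 (8 of 13 rose, 9 adjusted over the list alone), with VWF at 1.47 ± 0.23. Chemokines had a median of 0.43 (8 of 31 rose, 9 adjusted over the list alone). CCL21 was at 1.81 ± 0.34, CCL14 at 1.98 ± 0.39, CCL18, a macrophage product, at 1.54 ± 0.34 and CXCL12 at 1.31 ± 0.28. Macrophage genes had a median of 0.50 (4 of 19 rose, 8 adjusted over the list alone), with CD163 at 1.91 ± 0.34 and the complement gene C1QC at 1.51 ± 0.39, while CD68 was at 0.15 ± 0.18. Type I interferon response genes had a median of 0.64, above 0 in 5 of 5 biopsies (10 of 19 rose, 14 adjusted over the list alone), with IFI44L at 1.0 ± 0.18 and XAF1 at 0.86 ± 0.14. The largest rises of single genes included the iron exporter SLC40A1 at 2.0 ± 0.38, the selenoproteins GPX3 at 1.68 ± 0.41 and SELENOP at 1.58 ± 0.37, and the complement gene C7 at 1.53 ± 0.37. GIMAP7, a lymphocyte GTPase, was at 1.54 ± 0.27. Granulocyte genes had a median of 0.52 (0 of 8 past the threshold, adjusted p = 0.0399, and 0.374 with an estimated correlation), and their call ended without biopsy 1 (0.17, adjusted p = 0.248) or 5 (adjusted p = 0.103). Epithelium and fat genes had a median of 0.32 (1 of 8 rose, the keratin KRT5 at 0.94 ± 0.24, adjusted p = 0.0425 for the list, and 0.412 with an estimated correlation), and their call ended without biopsy 1 (adjusted p = 0.0811) or 2 (adjusted p = 0.0578).

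Part of the germinal centre, follicular dendritic and growth genes fell in T-rich tiles, that is, were higher in B-rich tiles. As whole lists, germinal centre, follicular dendritic, proliferation, cell cycle, oxidative phosphorylation, MYC target and FL genes had adjusted p of 0.347 with an estimated correlation. Germinal centre B cell genes had a median of -1.12, below 0 in 5 of 5 biopsies (9 of 14 fell, 12 adjusted over the list alone). BCL6 was at -1.21 ± 0.21, ELL3 at -1.79 ± 0.39, BCL7A at -1.49 ± 0.33, MME (CD10) at -1.43 ± 0.27 and LRMP at -1.39 ± 0.28. Follicular dendritic cell genes had a median of -0.90 (5 of 8 fell, 6 adjusted over the list alone), with FDCSP at -1.83 ± 0.38 and the complement receptor CR2 at -1.55 ± 0.31. Proliferation genes had a median of -0.75 (16 of 37 fell, 35 adjusted over the list alone) and further cell cycle genes of -0.58 (11 of 33 fell, 28 adjusted over the list alone), with E2F1 at -1.19 ± 0.27. Oxidative phosphorylation genes had a median of -0.47 (7 of 22 fell, 20 adjusted over the list alone). MYC targets had a median of -0.56 (4 of 15 fell, 15 adjusted over the list alone), with NME1 at -0.98 ± 0.24. Genes recurrently altered in FL had a median of -0.38 (3 of 16 fell, 5 adjusted over the list alone). Activated B cell genes had a median of -0.24 (1 of 15 fell, CD83 at -1.18 ± 0.24, adjusted p = 0.0451 for the list, and 0.623 with an estimated correlation). Their call ended without biopsy 2 (adjusted p = 0.0578) or 4 (-0.11, adjusted p = 0.605). Other large falls were AFF2 at -1.84 ± 0.40, BMP7, a growth factor, at -1.53 ± 0.28, BCL11A, a B cell transcription factor, at -1.43 ± 0.37, and SCARA5, a ferritin receptor, at -1.40 ± 0.22.

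Interferon gamma response genes had a median of 0.51 between the tile classes, with 1.26, 0.55, 0.16, -0.53 and 0.43 in biopsies 1 to 5 (3 of 20 rose, adjusted p = 0.0521). Without biopsy 3 the adjusted p was 0.0332, and without biopsy 4 the median was 0.65 (adjusted p = 0.000107). CXCL10 was at 0.68 ± 0.37, CXCL9 at 0.59 ± 0.46 and CCL19 at 0.63 ± 0.34 (adjusted p of 0.218, 0.376 and 0.215). CXCL13 was at -0.23 ± 0.33, MYC at -0.39 ± 0.16 and BCL2 at -0.47 ± 0.22 (adjusted p of 0.637, 0.128 and 0.165), and CD68 had 0.565. T zone stroma had a median of 0.97 (2 of 4 rose, adjusted p = 0.0563) and dendritic cells of 0.60 (2 of 12 rose, adjusted p = 0.0507). Without biopsy 4 both passed (adjusted p = 0.00764 and 0.00294). Fibroblasts had a median of 0.18 (2 of 14 rose, adjusted p = 0.0746), and passed without biopsy 4 (0.0163) or 5 (0.0419). Stress genes had a median of 0.33 (1 of 13 fell, adjusted p = 0.0507), and passed without biopsy 3 (0.0153). Glycolysis and hypoxia genes had a median of -0.34 (1 of 12 fell, adjusted p = 0.0521), and passed without biopsy 2 (0.0464) or 5 (0.0226). Plasma cells were at 0.11 (2 of 11 rose and 1 fell), MHC class I at -0.15 (0.05 scaled by library size alone), and naive and mantle B cells at a median of 0.12 and a mean of -0.02 (1 of 9 rose). Checkpoint ligands had a median of -0.01 (0.19 scaled by library size alone) with a test pointing up (1 of 11 rose).

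In all, 676 genes rose and 907 fell in T-rich against B-rich tiles, of 17995 tested with edgeR (656 and 851 of them with 1 sign in 5 of 5 biopsies). The smallest adjusted p was 0.0396, and the genes past the threshold named with a value lay between it and 0.0471. The count rests on 4 of the 5 biopsies: it was 0 without biopsy 1, 2, 3 or 4 and 1227 without biopsy 5. Of the 1583 called genes, 1582, 1581, 1583 and 1583 kept their sign with an unadjusted p under 0.05 without biopsies 1 to 4. The count was 3542 with the DESeq2 test, 2002 in biopsies 1 and 2 alone and 0 in biopsies 3 to 5 alone (edgeR, smallest adjusted p of 0.349). The 2002 come from a fit of 2 biopsies, under the least of 3, and are not firm. It was also 0, with the smallest adjusted p in brackets, with DESeq2 size factors (0.0542), tiles of 6 bins (0.0549) or 20 bins (0.0604), tiles in the middle of the UMIs per bin (0.0503), genes of split detection left out (0.0602) and no replicate block (0.9999). Library size alone gave 1333 rises and 214 falls, moved the median of all genes from 0.02 to 0.22, and ended the calls of granulocytes (adjusted p = 0.173) and epithelium (0.144) and gave a call for glycolysis (0.0167).

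Camera's calls between tile classes, of which 0 passed with an estimated correlation, had adjusted p = 5.47e-13 for proliferation, 9.77e-10 for cell cycle and cytotoxic, 4.48e-08 for oxidative phosphorylation, 2.23e-07 for type I interferon and germinal centre, and 4.78e-07 for MYC target genes. They had adjusted p = 5.93e-07 for endothelial and chemokine, 6.25e-05 for macrophage and FL, 0.000162 for exhaustion and 0.000724 for naive T cell genes. They had adjusted p = 0.00113 for follicular helper and follicular dendritic, 0.00565 for regulatory T cell and 0.00574 for cytokine genes (0.0529 without biopsy 5). Adjusted p was 0.347 with an estimated correlation for each called list except granulocytes (0.374), epithelium (0.412) and activated B cells (0.623). The smallest adjusted p of fry was 0.0616. In biopsies 1 and 2 and in biopsies 3 to 5 the medians were 1.79 and 0.87 for cytotoxic, -1.64 and -0.69 for germinal centre, and 0.59 and 0.53 for type I interferon genes. They were -0.62 and -0.48 for MYC target, -0.54 and -0.41 for oxidative phosphorylation, and 0.89 and 0.04 for interferon gamma genes.

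**Figure D3:**
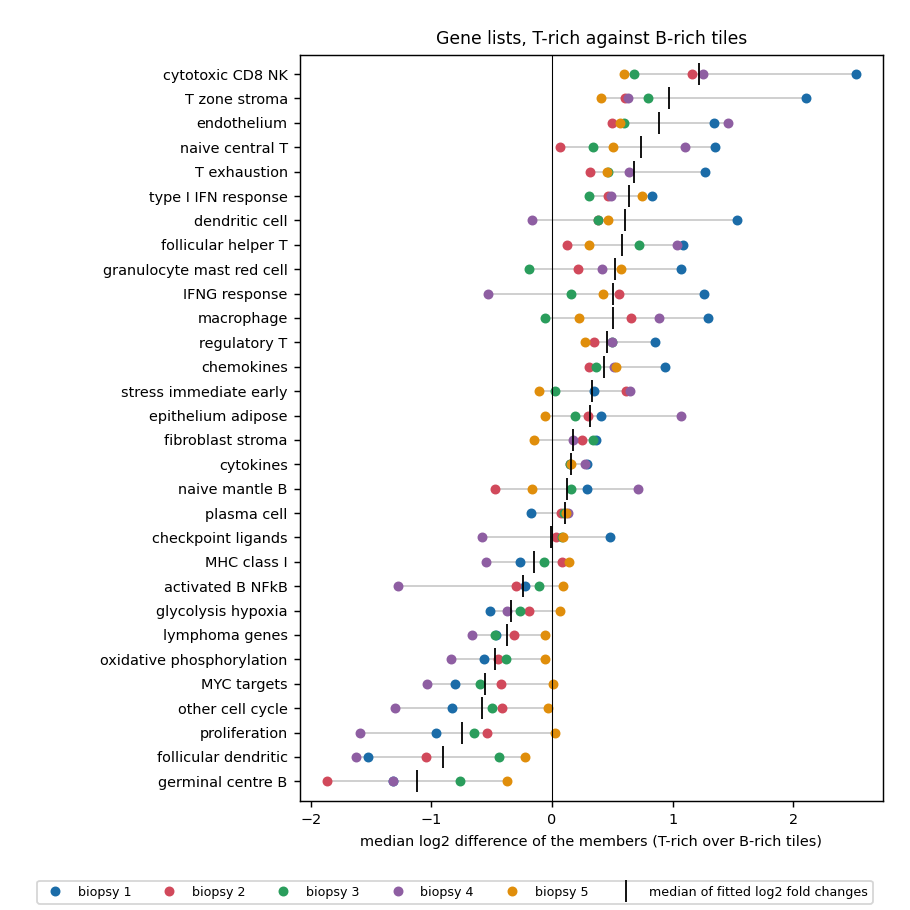
Median log2 fold change of each gene list in T-rich against B-rich tiles, with 1 point per biopsy and a bar for the value of the fit over 5 biopsies. Cytotoxic genes (1.22) lie above 0 and germinal centre B cell genes (-1.12) below 0 in 5 of 5 biopsies, while interferon gamma response genes range from -0.53 in biopsy 4 to 1.26 in biopsy 1.

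To ask how the area difference looks where B cells dominate, high against low proliferation areas in B-rich tiles were compared. MYC targets had a median of 0.76 (15 of 15 adjusted over the list alone), with NME1 at 1.30 ± 0.37 (SE, n = 5). Oxidative phosphorylation genes had a median of 0.66 (20 of 22 adjusted over the list alone), with ATP5F1B at 0.80 ± 0.20 and COX6C at 0.69 ± 0.14. Glycolysis and hypoxia genes had a median of 0.56 (5 of 12 adjusted over the list alone), with ENO1 at 1.16 ± 0.27 and the angiogenic factor VEGFA at 0.97 ± 0.24. Cell cycle genes had a median of 1.02 (29 of 33 adjusted over the list alone), with STMN1 at 1.10 ± 0.22 and HMGB2 at 1.11 ± 0.24. Biopsy 1 was highest for these 4 lists, at 1.82, 1.28, 1.47 and 1.86, and biopsy 5 lowest, at 0.12, 0.0846, -0.00796 and 0.34. MYC was at 0.88 ± 0.28, EZH2 at 0.99 ± 0.30 and RELB at 0.69. The B lineage list itself was at 0.06, with a mean of -0.01 (-0.20 scaled by library size alone). Type I interferon response genes had a median of -0.46, below 0 in 5 of 5 biopsies, with XAF1 at -0.48. Of their 19 members 0 passed adjusted over the list alone, and the list did not pass with an estimated correlation. Naive and mantle B cell genes were at -0.56. KLF2, a transcription factor of resting lymphocytes, was at -1.45 ± 0.34, FOS at -0.88 ± 0.28 and CCL21 at -0.66. Macrophage genes had a median of 0.41 (0 of 19 adjusted over the list alone), with SPP1 at 1.64 ± 0.55, APOE at 0.79, CD68 at 0.72 and CSF1R at 0.47.

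Within B-rich tiles 0 of 17944 genes passed the edgeR test, 5886 had an unadjusted p under 0.05 (3196 without biopsy 1, 3625 without biopsy 3) and DESeq2 called 418. Areas of 240 µm together with tiles of 6 bins gave 1420 (1073 up, 347 down), and tiles of 6 bins alone gave 0 with edgeR (5868 at an unadjusted p under 0.05). As reported, the smallest adjusted p was 0.0814. With an estimated correlation 0 lists passed (adjusted p from 0.650 to 0.790 with an estimated correlation for the lists called below), and the smallest adjusted p of fry was 0.0547. With the preset correlation camera called cell cycle (adjusted p = 2.05e-11), oxidative phosphorylation (1.57e-08), MYC target (1.22e-06), type I interferon (3.54e-06), naive and mantle B cell (0.0024) and activated B cell genes (median 0.53, 0.00647). It called glycolysis (0.0125), whose call ended without biopsy 1 (0.0722), follicular helper T cells (-0.43, 0.00836; 0.169 without biopsy 1) and macrophages (0.0426; 0.996 without biopsy 1 and 0.166 without biopsy 3). It called T lineage (-0.35, 0.0256) and naive T cells (-0.54, 0.0369), whose calls ended without biopsy 3 (0.0596 and 0.0701) or 4 (0.303 and 0.198). It called FL genes (0.32, 0.0411), whose call ended without biopsy 2 (0.0774) or 3 (0.0755), and chemokines (-0.13, 0.0256). Germinal centre genes were at 0.46 (0.252). Without biopsy 1, cytotoxic (-0.21, 0.197), endothelial (-0.24, 0.165) and interferon gamma response genes (0.20, 0.252; -0.05 scaled by library size alone) passed, with adjusted p of 0.007, 0.000354 and 0.0311. Epithelium genes (-0.48, 0.0932) passed without biopsy 3 (0.0336). Library size alone moved the median of all genes from -0.03 to -0.28 and ended the T lineage (0.133), follicular helper (0.0742), naive T cell (0.156) and chemokine calls (0.172). In biopsies 1 and 2 and in biopsies 3 to 5 the medians were 1.11 and 0.49 for MYC targets, 0.87 and 0.42 for oxidative phosphorylation, and -0.81 and -0.23 for type I interferon genes. Biopsy 4 gave 30 B-rich tiles in low areas, the fewest of any class.

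To ask the same where T cells dominate, high against low proliferation areas in T-rich tiles were compared. Cell cycle (median 0.71), oxidative phosphorylation (0.42) and MYC target genes (0.52) were above 0 in 5 of 5 biopsies, with 21 of 33, 4 of 22 and 0 of 15 past the threshold adjusted over the list alone. Biopsy 1 stood apart for all 3, with 1.88, 1.22 and 1.44 against 0.23 to 0.68, 0.11 to 0.38 and 0.12 to 0.43 in the others, and without it the medians were 0.46, 0.22 and 0.25. STMN1 was at 0.81 ± 0.21 (SE, n = 5; 1.72 in biopsy 1 and 0.45 to 0.68 in the others), ATP5F1B at 0.65 ± 0.20, COX6C at 0.47 ± 0.14 and NDUFB3 at 0.50. Germinal centre (0.48), activated B cell (0.32) and FL genes (0.27) had medians above 0 in 3, 4 and 4 of 5 biopsies, with 0 of 14, 1 of 15 and 0 of 16 past the threshold adjusted over the list alone. EZH2 was at 0.83 ± 0.30, with 2.31 in biopsy 1 and 0.31 to 0.75 in the others. T lineage genes were at -0.54 and type I interferon response genes at -0.49, both below 0 in 5 of 5 biopsies, with TCF7 at -0.95 and OAS3 at -0.53. CCL21 was at -1.28 ± 0.48, CXCL12 at -0.85 ± 0.29 and FOS at -0.91 ± 0.28. S100A9, a neutrophil and monocyte gene, was at 1.23 ± 0.47 and CD68 at 0.57.

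Within T-rich tiles 0 of 17944 genes passed the edgeR test, 1824 had an unadjusted p under 0.05 (675 without biopsy 1, 967 without biopsy 3) and DESeq2 called 0. The smallest adjusted p was 0.486. With an estimated correlation 0 lists passed (adjusted p from 0.627 to 0.634 with an estimated correlation for the lists called below), and the smallest adjusted p of fry was 0.346. With the preset correlation camera called cell cycle (adjusted p = 1.66e-19), oxidative phosphorylation (2.35e-11), MYC target (3.69e-08), activated B cell (0.00145), germinal centre (0.00275), T lineage (0.00594) and FL genes (0.00856). It called type I interferon genes (0.000333), whose call ended without biopsy 5 (-0.29, 0.138). Calls that ended without biopsy 1 were follicular helper T cells (-0.50, 0.00783; 0.153 without it), endothelium (-0.35, 0.0104; 0.0679), macrophages (0.24, 0.0218; 0.169) and naive and mantle B cells (-0.61, 0.0259; 0.295). Without biopsy 3 the macrophage (0.353) and naive and mantle calls (0.0508) ended too. The glycolysis call (0.14, 0.0292) ended without biopsies 1 to 4 (0.169, 0.0539, 0.0563 and 0.0557). Interferon gamma response genes (0.07, 0.0755; -0.06 scaled by library size alone) passed without biopsy 1 (0.00676) or 5 (0.0274), naive T cells (-0.46, 0.101) without biopsy 2 (0.0377), and fibroblasts (0.06, 0.776) without biopsy 1, at -0.24 (0.0177). Library size alone moved the median of all genes from -0.07 to -0.19 and ended the naive and mantle call (0.122). In biopsies 1 and 2 and in biopsies 3 to 5 the medians were 0.86 and 0.25 for MYC targets, 0.69 and 0.28 for oxidative phosphorylation, and -0.53 and -0.51 for type I interferon genes.

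To test whether the area difference itself differed between the tile classes, the difference of the area effect between T-rich and B-rich tiles was taken. MYC target genes had a median difference of -0.28, below 0 in 5 of 5 biopsies, and oxidative phosphorylation genes of -0.21, with adjusted p of 0.573 and 0.623. The chemokine CCL19 was at -0.70 ± 0.41 (SE, n = 5) and BCL2 at 0.11 ± 0.73. Here 0 of 17944 genes passed the edgeR test, 169 had an unadjusted p under 0.05 (260 without biopsy 2, 62 without biopsy 3, 111 without biopsy 5) and DESeq2 called 0. Camera called 0 lists, with a smallest adjusted p of 0.2. Without biopsy 3 follicular dendritic cell genes were at 0.34 (adjusted p = 0.0375), and without biopsy 5 type I interferon response genes at 0.20 (0.000292), where with all biopsies their median was -0.10 (0.02 scaled by library size alone) and the test pointed up. Library size alone moved the median of all genes from -0.07 to 0.06. The area effects in B-rich and in T-rich tiles are thus not shown to differ for any gene or list.

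To ask which programs share a location, list scores were correlated across tiles within each biopsy. Cytotoxic and exhaustion genes had a mean Spearman correlation of 0.529, above 0 in 5 of 5 biopsies, as did T zone stroma and naive T cell genes (0.421, 5 of 5). Cytotoxic and proliferation genes were at -0.326, above 0 in 1 of 5. The interferon gamma response list was at 0.364 with macrophage genes and 0.325 with CD74, the invariant chain of MHC class II, and at 0.214 with exhaustion genes, each above 0 in 4 of 5. Its correlation with cytotoxic genes was 0.211, with 0.619, 0.630, 0.112, -0.585 and 0.164 in biopsies 1 to 5. With proliferation genes it was 0.0813, with -0.590, -0.128, 0.239, 0.772 and -0.0553. Without the 4 most abundant members in each biopsy, a test chosen after the values were seen, it was -0.672, -0.185, 0.0247, -0.176 and -0.0172. Follicular dendritic cell genes were at 0.12 with follicular helper, 0.142 with germinal centre and 0.00521 with proliferation genes. Proliferation genes were at -0.0307 with macrophage and -0.190 with regulatory T cell genes. In biopsies 1 and 2 and in biopsies 3 to 5 the means were 0.6 and 0.478 for cytotoxic with exhaustion, and 0.495 and 0.369 for T zone with naive T cell genes. For interferon gamma genes they were 0.624 and -0.130 with cytotoxic, and -0.383 and 0.384 with proliferation genes. The exact two-sided sign-flip permutation test over 5 biopsies cannot go below 1 in 16, so no pair can pass 0.05, and the adjusted p of the 13 pairs were 0.325 or more. Tiles of a section are not independent replicates.

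**Figure D4:**
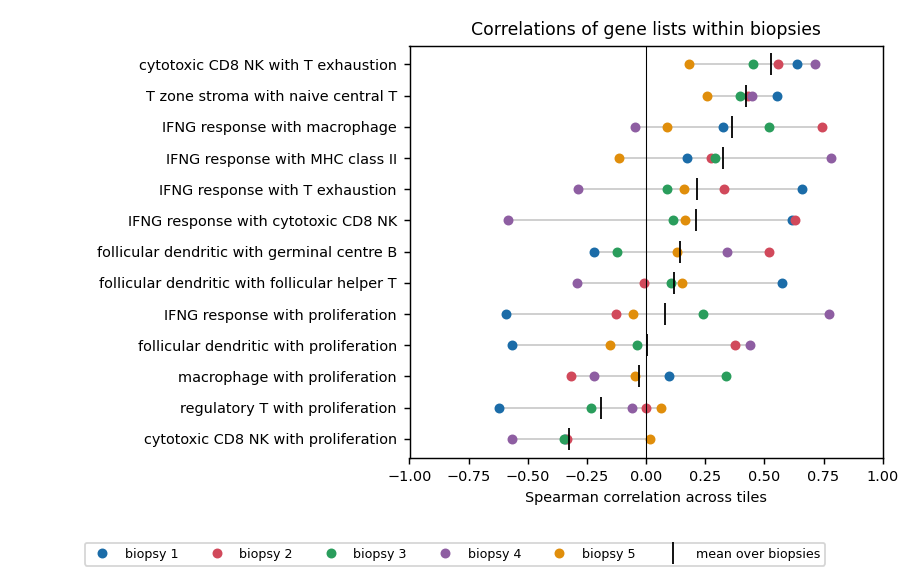
Spearman correlation across tiles of each of the 13 pairs of gene lists, with 1 point per biopsy and a bar for the mean over 5 biopsies. Cytotoxic and exhaustion genes lie above 0 in 5 of 5 biopsies, and the interferon gamma response list ranges from -0.590 in biopsy 1 to 0.772 in biopsy 4 with proliferation genes.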

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

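All tests of explanations in this part, and the counts over other splits, were chosen only after the result was seen. Of 317 values checked over the 5 biopsies (levels of lists, correlations of pairs of lists, and medians of lists and changes of named genes in each comparison), 36 had 1 biopsy apart from the other 4 by Dixon's ratio. Chance alone sets 1 biopsy apart in about 1 in 20 groups, here 15.85. The values share genes and sections, and the named genes were picked after their values were seen. Setting 36 beside 15.85 is thus no test. Biopsy 1 was the one apart in 29 of the 36, biopsy 4 in 4, and biopsies 2, 3 and 5 in 1 each.

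Levels apart from the rest were the T lineage list in biopsy 1 (2452 CPM against 4783 to 5631), MYC targets in biopsy 1 (3274 CPM against 1144 to 1384, or 2647 against 1122 to 1364 without its 2 members of split detection, NCL and FBL) and dendritic cell genes in biopsy 2 (2986 CPM against 116 to 390). In the last, 2 of the 12 members, CCL17 and CCL22, made up 2670 CPM, and the other 10 were at 317 CPM against 72.8 to 326. Between high and low proliferation areas, biopsy 1 stood apart with medians of -1.57 for dendritic cell, 0.91 for fibroblast, -0.89 for cytokine, -1.02 for chemokine and 1.25 for glycolysis genes, and with -3.76 for BCL2, which lay between -0.06 and 1.15 in the others. Biopsy 4 stood apart for checkpoint ligands (0.47), and biopsy 5 for CXCL12 (0.0761 against -1.71 to -1.39). Between T-rich and B-rich tiles, biopsy 1 stood apart for plasma cell genes (-0.18), T zone stroma (2.10), GZMK (2.62), IFNG (1.37), LAG3 (2.65) and XAF1 (1.54), and biopsy 4 for activated B cell genes (-1.27).

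Within B-rich tiles, biopsy 1 stood apart for T lineage (-1.75), naive and mantle B cell (-2.34), follicular helper T cell (-1.98) and epithelium genes (-1.29) and for FOS (-1.59). Within T-rich tiles it stood apart for cell cycle (1.88), follicular helper T cell (-1.78), fibroblast (1.06), cytokine (-0.66), MYC target (1.44) and oxidative phosphorylation genes (1.22), for STMN1 (1.72) and for EZH2 (2.31). In the difference between these effects, biopsy 1 stood apart for macrophage (-0.58) and follicular dendritic cell genes (1.82), biopsy 4 for exhaustion (0.43) and cytokine genes (-0.42), and biopsy 3 for regulatory T cell genes (-0.24).

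The first pattern weighed is the higher level of MYC target and oxidative phosphorylation genes in high proliferation areas. The spatial grain of the score map alone is argued against: in 30 maps of the same score moved or mirrored on the tissue, the highest MYC target median was 0.349 against 0.733 with the real map, and the highest oxidative phosphorylation median 0.279 against 0.686. Whether more B cells in high areas are the whole source cannot be decided. Inside B-rich tiles the MYC target median was 0.755 where the B lineage list was at 0.06. These tiles were picked by the ratio of B to T lineage genes and did not equalise cell content. The T lineage median inside them was -1.75 in biopsy 1 and -0.45 to 0.04 in the others. With the score divided by the B lineage list, the MYC target and oxidative phosphorylation medians were smaller but above 0. More UMIs per bin are argued against as the whole source. Among tiles of high and low areas matched on UMIs per bin the MYC target median was 0.674, above 0 in 5 of 5 biopsies. The score itself selects cell cycle genes, and growth genes that move with the cycle were not separated from it, so that stays open. No biological explanation was tested, since the labels give no groups.

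The second pattern is the interferon gamma response list, which went with proliferation across tiles in biopsy 4 (0.772) and against it in biopsy 1 (-0.590). In biopsy 4 a few abundant members are a candidate explanation: CIITA, TAP1, PSMB9 and PSMB8 made up 58.5% of the list, 9 of 20 members were below 0 (NLRC5 -0.465, GBP5 -0.409), and without the 4 the correlation was -0.176 (0.422 with all 20 weighted alike) and that with cytotoxic genes 0.232 in place of -0.585 (-0.126 weighted alike). In biopsy 1 abundant members are argued against (-0.672 without its 4), and so is the share of B cells (-0.547 given the log ratio of the B to the T lineage list). In biopsy 4 the share of B cells cannot be told apart from the pattern, since given that ratio the correlation was 0.422, or 0.483 to 0.601 of its size over areas drawn again, and the ratio correlated at 0.903 with CIITA, 0.659 with TAP1, -0.603 with NLRC5 and -0.536 with GBP5. UMIs per tile are argued against in biopsy 4 (0.723 given log UMIs per tile), while the different gene detection of biopsies 1 and 2 and of biopsies 3 to 5 cannot be told apart from differences between biopsies (exact permutation p of 0.2 over the 10 ways to form such sets), and no biological explanation was tested.

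The third pattern is the number of genes at least 4-fold apart between high and low areas, at 20 CPM or more, which was 445, 1, 9, 84 and 0 in biopsies 1 to 5. Inside B-rich tiles biopsy 1 had 452 such genes and the highest of the others 21. This cannot decide whether more B cells in high areas are the source, since B-rich tiles did not equalise cell content. In biopsy 1 the T lineage median was still -1.75 between high and low areas inside them. More UMIs per bin are argued against. Among tiles of high and low areas matched on UMIs per bin, biopsy 1 had 375 such genes and the highest of the others 35. The matched medians were 157.4 and 156.9 UMIs per bin in biopsy 1. Whether the steeper proliferation score of biopsy 1 (3.75-fold between its areas) accounts for the number cannot be decided. The log2 limit was scaled to each biopsy's own score difference (2, 0.59, 1.11, 1.23 and 0.45 in biopsies 1 to 5). The numbers were then 445, 575, 153, 570 and 76. A lower limit admits more genes whatever the source, and biopsies 3 and 5 stayed below biopsy 1. No biological explanation was tested.

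The sums of a biopsy can be swapped in 16 ways, the real one included, which cannot give a share under 0.05. For T-rich against B-rich tiles the real split gave 1583 genes past the threshold and the highest other 0, so 1 of the 16 gave as many. For the other 4 comparisons the real count was 0, which 16 of 16 splits reach. At an unadjusted p under 0.05 the real split and the highest other gave 6583 and 4238 genes between areas, 6068 and 4245 between tile classes, 5886 and 4686 within B-rich tiles, 1824 and 1071 within T-rich tiles, and 169 and 143 for the difference.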

How the results depend on the processing

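Chosen only after the data were seen were the settings with biopsies 2, 3 and 5 alone, biopsies 1, 3 and 4 alone, biopsies 1 and 2 alone and biopsies 3 to 5 alone, with genes of split detection left out, and with list scores by mean rank. For gene lists, settings other than DESeq2 size factors, biopsies left out in turn, an estimated correlation and fry were also added then. Over all settings, 2003 of 2599 values of named genes kept their direction and their side of the threshold, 496 lost the threshold, 60 gained it and 40 changed sign. Of 3636 list tests these numbers were 3256, 250, 113 and 17, where the last holds tests past the threshold on at least 1 side whose direction changed. Of 3328 list medians, 284 changed sign (40, 21, 61, 58 and 104 in the 5 comparisons), 4 of them of lists called as reported. Of 252 counts 211 stayed within 1.5 times the reported count and 41 did not. Of 169 correlations 168 moved by less than 1 SD between biopsies, as did 264 of 264 list levels. Leaving 1 biopsy out cannot move a mean over 5 biopsies by 1 SD, nor can taking biopsies 3 to 5 alone for correlations. Those settings could not fail, so these numbers do not measure how firm the values are. The cause was not tested for any of the changes below, except where a setting uses fewer biopsies.

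For high against low proliferation areas the reported count is 0. The DESeq2 test gave 1991 genes and biopsies 1 and 2 alone 116, the latter from a fit of only 2 biopsies. Changes of sign of the named genes and of list medians there were as follows. Library size alone: CCL19 -0.15, CXCL9 -0.0699, CXCL10 -0.20 and CXCL13 -0.0570, and the medians of 6 lists not past the threshold: interferon gamma response (-0.18), macrophages (-0.21), follicular dendritic cells (-0.22), fibroblasts (-0.13), checkpoint ligands (-0.11) and MHC class I (-0.03). No replicate block: CXCL9 -0.35 and FOXP3 0.0153, and the medians of plasma cell (0.0834) and regulatory T cell genes (0.0153). Proliferation score per B lineage CPM: S1PR2 -0.0606, BCL6 -0.22, IL7R 0.0295, CD8A 0.30, GZMA 0.27, CD163 0.90, IFNG 0.16, LAG3 0.46, CXCL13 -0.47 and CR2 -0.59. With that score the lists of B lineage (-0.75), germinal centre (-0.25) and cytotoxic genes (0.30) passed the threshold in the other direction (adjusted p = 5.27e-11, 0.0431 and 6.20e-10). The B lineage list is the divisor of that score, so changes of B cell genes and of genes of other cells are not independent of it. Lists of exhaustion (0.17), follicular dendritic (-0.66) and stress genes (0.24) passed in the other direction where they had not passed. The tests of T lineage (-0.0520), endothelial (-0.0154) and chemokine genes (-0.0981) changed direction and no longer passed, and the medians of dendritic cell (0.0750) and granulocyte genes (0.00414), past the threshold in neither case, changed sign. Biopsies 2, 3 and 5 alone: CXCL10 -0.11, BCL2 0.0862, the fibroblast list -0.25 and the naive and mantle B cell list 0.0491. Biopsies 1 and 2 alone: CCL19 -0.23, CXCL9 -1.11, CXCL10 -0.72 and CXCL13 -0.27, and the lists of interferon gamma response (-0.51), follicular dendritic cell (-0.52), plasma cell (0.48), macrophage (-0.0709) and checkpoint ligand genes (-0.0758). Biopsies 3 to 5 alone: LAG3 0.10 and BCL2 0.45, and the lists of fibroblast (-0.21), macrophage (-0.0177) and dendritic cell genes (0.0289). The follicular dendritic cell list was at -0.00861 in the middle part of UMIs per bin, -0.0177 with 2 classes in place of 3 and -0.0183 in biopsies 1, 3 and 4 alone, and the macrophage list at -0.0154 with areas of 240 µm and tiles of 6 bins. With biopsies 1 to 5 left out in turn, 2, 1, 3, 4 and 0 list medians changed sign. For the other comparisons, list medians that changed sign past the threshold in neither case are given only in the numbers above.

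For T-rich against B-rich tiles the reported count is 1583. It was 0 with DESeq2 size factors (smallest adjusted p of 0.0542), tiles of 6 bins (0.0549), tiles of 20 bins (0.0604), tiles in the middle part of UMIs per bin (0.0503), genes of split detection left out (0.0602) and biopsies 3 to 5 alone (0.349), and 0 with no replicate block for the pairing of the sums (0.9999, 370 genes at an unadjusted p under 0.05). The 1583 genes kept their sign with an unadjusted p under 0.05 in 1583 cases with DESeq2 size factors and with tiles of 6 or 20 bins, 1578 in the middle part of UMIs per bin, 1240 in biopsies 3 to 5 alone and 300 with no block. The count was 3542 with the DESeq2 test, 449 with 2 classes in place of 3, 56 in biopsies 2, 3 and 5 alone and 281 in biopsies 1, 3 and 4 alone. CXCL13 changed sign in biopsies 2, 3 and 5 alone (0.13), and CXCL9 (-0.17) and CD68 (-0.15) in biopsies 3 to 5 alone. The checkpoint ligand list passed in biopsies 1 and 2 alone with the other sign (0.37).

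Within B-rich tiles the reported count is 0, and it was 418 with the DESeq2 test, 1420 with areas of 240 µm (30 bins) together with tiles of 6 bins, 0 with tiles of 6 bins alone (smallest adjusted p of 0.0800, 5868 genes at an unadjusted p under 0.05) and 1 in biopsies 1, 3 and 4 alone. With the score per B lineage CPM, the test of cytotoxic genes changed direction within B-rich (0.13) and T-rich tiles (0.16), as did that of B lineage genes within T-rich tiles (-0.29) and of cell cycle genes for the difference (-0.0848). The B lineage list passed there within B-rich tiles with the other sign (-0.36), which follows in part from its place as the divisor of the score. Within T-rich tiles the fibroblast list changed sign in biopsies 2, 3 and 5 alone (-0.18) and in biopsies 3 to 5 alone (-0.24). The naive and mantle B cell list no longer passed in biopsies 2, 3 and 5 alone, with a median of 0.00356, and the B lineage list passed in biopsies 1 and 2 alone (0.40). For the difference of the area effects, BCL2 changed sign with no replicate block (-0.0283), in biopsies 2, 3 and 5 alone (-0.0667) and in biopsies 3 to 5 alone (-0.26). Type I interferon genes passed with the other sign in biopsies 1, 3 and 4 alone (0.18), in biopsies 1 and 2 alone (0.27) and without biopsy 5 (0.20), and germinal centre genes in biopsies 1 and 2 alone (0.41).

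The numbers of lists called by camera were 15, 20, 13, 13 and 0 in the 5 comparisons. With an estimated correlation in camera and with fry in its place they were 0 in each. For the difference, biopsies 2, 3 and 5 alone gave 1, biopsies 1, 3 and 4 alone 1, biopsies 1 and 2 alone 7, 4 classes in place of 3 gave 3, areas of 240 µm with tiles of 6 bins 2 and the score per B lineage CPM 3. Pairs of lists correlated with 1 sign in every biopsy numbered 2, with mean ranks of members 4, and in biopsies 1 and 2 alone 9.

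With each biopsy left out in turn, the lowest and highest values were, between areas, -0.10 to 0.22 for CCL19, -0.27 to 0.58 for CXCL9, -0.32 to 0.29 for CXCL10, -0.21 to 0.56 for CXCL13 and -0.70 to 0.35 for BCL2. Between tile classes they were 0 to 1227 for the count and -0.47 to 0.13 for CXCL13, within T-rich tiles -0.24 to 0.17 for the fibroblast list, and for the difference -0.23 to 0.42 for BCL2 and 0 to 1 for called lists. Correlated pairs numbered 2 to 5, and lists more than 2-fold apart between biopsies 17 to 26. Genes at an unadjusted p under 0.05 numbered 2695 to 7014 between areas, 3196 to 5665 within B-rich tiles, 675 to 2153 within T-rich tiles and 62 to 260 for the difference.

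With 4 classes in place of 3 and with tiles of 20 bins, 1 biopsy had a class under 10 tiles inside B-rich or T-rich tiles, so those fits used 4 biopsies. Depth bears on the thinnest sums: 685530 UMIs in biopsy 4's B-rich tiles of low areas, where genes of low level have few counts.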

Other observations

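The genes and values in this part were picked only after the data were seen, and no test of a cause was made. No list of serine, folate or nucleotide synthesis was tested, and the 8 genes here were picked by their values. Higher in high than in low proliferation areas in 5 of 5 biopsies were PHGDH, the first enzyme of serine synthesis, at a log2 fold change of 1.40 ± 0.37 (SE, n = 5), SHMT2 at 1.18 ± 0.31 and MTHFD2 at 1.17 ± 0.25, which both serve mitochondrial folate metabolism, and IMPDH2, which limits guanine nucleotide synthesis, at 1.20 ± 0.27. CDT1, which licenses replication origins, was at 2.05 ± 0.41, and the chromatin protein HMGA1 at 1.57 ± 0.35. The elastic fibre genes ELN (elastin) and FBLN5 (fibulin 5) were lower in 5 of 5 biopsies, at -1.41 ± 0.34 and -1.14 ± 0.22. None of these 8 genes passed the edgeR test (adjusted p = 0.114 each), which called 0 genes there, with 6583 at an unadjusted p under 0.05 and 1991 by DESeq2.

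CCL17, a chemokine that draws CCR4-bearing T cells, was at 2527 CPM over the high and low areas of biopsy 2 and at 8.83 to 56.9 CPM in the others. In biopsy 2 it was at 3665 CPM in high and 1283 CPM in low proliferation areas, and at 3597 CPM in B-rich and 1035 CPM in T-rich tiles. It was counted in 98.0% of the tiles of biopsy 2 and in 18.6% to 46.5% of those of the others. Across the tiles of biopsy 2 its Spearman correlation was 0.753 with CCL22, which binds the same receptor, 0.650 with the B cell gene CD79B, 0.620 with the log ratio of the B to the T lineage list, 0.581 with IL4R and 0.565 with CD40. The correlation with that log ratio was 0.0963, -0.00262, 0.615 and -0.0403 in biopsies 1, 3, 4 and 5, and in biopsy 4 it was 0.247 with CCL22 and 0.0893 with IL4R. In biopsy 2 with the dendritic cell genes LAMP3 and FSCN1 the correlation of CCL17 was -0.0512 and 0.115, and with SLC40A1 and C1QC -0.625 and -0.481. CCL22 was at 417 CPM in high and 165 CPM in low areas of biopsy 2. Both genes are members of the dendritic cell list, which was at 2986 CPM in biopsy 2, and of the chemokine list.

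Within the B-rich tiles of biopsy 1, BCL2 was at 15.2 CPM in high and 387 CPM in low proliferation areas, TCL1A at 13.6 and 364 CPM and FCER2 (CD23) at 0.889 and 19.6 CPM. There the matrix genes POSTN and COL3A1 were at 174 and 3839 CPM in high and 4.58 and 343 CPM in low areas, and ELN at 11.7 and 165 CPM. BIK, a BH3-only gene, was at 395 CPM in high and 19.6 CPM in low areas of biopsy 1, and CD70 at 229 and 44.7 CPM in high and low areas of biopsy 4. Each of these is a value of 1 section, without a replicate.

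Between biopsies, 178 genes were at least 10-fold higher in biopsies 1 and 2 than in biopsies 3 to 5, and 0 the other way. With at least 20 CPM in both and under 2 CPM in all of the other 3 there were 86 genes, among them the B cell factor PAX5 with 405 and 316 CPM in biopsies 1 and 2 and at most 1.15 CPM in the others. By that second rule, the highest number in the other ways of dividing the 5 biopsies into 2 sets (15 in all) was 1. Of the 178 genes, 12 are members of the gene lists. Correlations between biopsies over genes were 0.914 to 0.949 within the 2 sets and 0.847 to 0.894 across them. Without the 178 genes they overlapped, with 0.913 to 0.948 within and 0.874 to 0.917 across. The labels name no difference in probe set or batch between the biopsies, and levels of these genes cannot be compared between the sets.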
